A study of Mus musculus with 18 samples.

How the data were processed

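RNA from 18 mouse melanoma samples was measured by sequencing of stranded mRNA libraries, 3 libraries in each of 6 groups. Per the labels' protocols, MO4 cells, a B16F10 melanoma line that carries ovalbumin, were placed under the skin of both hindlimbs of C57BL/6 mice on day 0 (100000 cells per side). Cells derived from induced pluripotent stem cells (iPSC-pMCs, here pMC) or the same kind of cells marked IFN-alpha (IFN-alpha-pMC) were injected beside the right tumour on days 5, 6 and 7 (1000000 cells each time), and tumour RNA was taken on day 11 with an RNeasy Plus kit. Control tumours received no cells. Groups were taken from the sample titles, which give the treatment, the side (right, beside which cells were injected, or left, the distant tumour) and a number from 1 to 3. Libraries are named by group and that number. The labels do not say that samples of a group came from separate animals, nor whether a right and a left sample with the same number came from the same mouse, so p-values measure the spread between these samples.

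The deposited values are raw counts of read pairs per Ensembl gene ID, 1 file per library, with no normalization, as the whole numbers and the counter's own messages in the files show. Per the submitters' processing notes, the tools named are bcl2fastq, CASAVA 1.8.2, FastQC, Trimmomatic 0.36, HISAT2 2.1.0, HTSeq 0.10.0 and DESeq2 1.20.0, and the genome build is mm9. The annotation release, the strand setting of the counter and the other counting options are not given in the sources used here, so reads of a gene and of an antisense gene on the same locus may not have been told apart. The counter's messages name 1 sequencing lane for all 18 libraries. Each file holds 37620 gene IDs and 5 summary rows. The summary rows were left out of library sizes and tests. Their shares of the read pairs were 4.04 to 12.21% for pairs in no feature, 2.28 to 2.93% for ambiguous pairs, 0.83 to 1.12% for low alignment quality, 1.73 to 2.41% for pairs not aligned and 18.38 to 24.34% for pairs aligned more than once, and 60.2 to 70.7% (median 64.8%) were assigned to a gene. Pairs that align more than once are not in the gene counts, so families of near-identical genes (granzymes, major histocompatibility complex class I, interferon alpha, alpha and beta globin) may be undercounted or split. The 37 mitochondrial gene IDs held 0.0% of the counts.

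Gene symbols came from a table of mouse gene names, GENCODE M21 on build GRCm38. They were matched by Ensembl ID for 32897 of the 37620 IDs, and 4723 IDs stayed without a symbol. No coordinates were used, because the reference was of another build than the files. Transcript length and GC content from the same annotation were known for 96.9% of the genes tested.

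In units of 1000000 counts, library totals ran from 14.35 to 23.43 (median 18.85). A library with a count of 0 allows up to 3 counts, which is 0.128 to 0.209 CPM (counts scaled to a library total of 1000000). Such floors and the intervals of ratios cover counting error only, because read pairs without molecular identifiers are not independent molecules. Where a group held 0 counts of a named gene the fold was computed against 3 counts summed over its 3 libraries and written as "at least". Where it held 1 to 3 counts, the ratio of summed counts per library total is given with its exact 95% binomial interval.

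Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (two-sided). Library sizes were scaled by trimmed means, genes were kept by filterByExpr at its defaults (14849 genes), and 1 model with a mean for each of the 6 groups was fitted to all 18 libraries (12 residual degrees of freedom, common dispersion 0.0564, biological coefficient of variation 23.7%). The p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and every adjusted p of a gene below comes from this test unless another is named. The standard error of a log2 fold change was its size divided by the square root of F. Mean CPM values are given with the SD over 3 libraries. Comparisons were IFN-alpha-pMC and pMC against control and against each other on each side, right against left within each treatment, and the difference between sides, which is the right effect minus the left effect.

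The gene lists were tested with camera from limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 28 lists with at least 5 tested members within a comparison. The 31 lists, written from textbook markers, were type I interferon response, interferon-gamma response, type I interferon genes, MHC class I presentation, MHC class II presentation, T cell markers, cytotoxic effector, T cell checkpoint and regulatory, NK cell, B and plasma cell, XCR1+ conventional dendritic cell (cDC1), activated dendritic cell, plasmacytoid dendritic cell, monocyte and macrophage, alternative macrophage activation, neutrophil, mast cell and basophil, lymphoid chemokines and lymphoid structure, melanocyte lineage, proliferation, fibroblast and extracellular matrix, endothelial, skeletal muscle, keratinocyte, adipocyte, erythroid and blood, hypoxia and glycolysis, apoptosis and p53 targets, immediate early and heat shock genes that respond to tissue handling, pluripotency and embryonic hematopoietic, and a sex check. A list score is the mean over a list's genes of the log2 CPM (prior count 2) centred on all 18 libraries.

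Genes were named by a rule. Part a took, per comparison, the 6 largest positive and 6 largest negative log2 fold changes past the threshold, with a mean CPM of at least 1 in the higher group and no overlap between the samples of both groups (the overlap condition was not used for the difference between sides), without numbered predicted genes. Part b took up to 4 members per list with the smallest p among those past the threshold, and for a list with none the member with the smallest p, by value. Part c was a preset set given by value (interferon response genes, T cell, NK, dendritic and myeloid markers, pigment genes, Mki67, Ckm and the interferon genes themselves).

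The test was checked on simulated counts drawn from the means, dispersions and library sizes of the real genes, with 50 genes changed at each of 4 fold sizes among 14849. Genes with a low mean CPM were not among those changed. Each gene varied independently around its mean, with the same spread in all 6 groups. The trends with transcript length or muscle content that the real libraries share were left out. The shares and false calls below hold for such counts only. For IFN-alpha-pMC against control on the right it recovered 4% of genes changed 1.5-fold, 38% at 2-fold, 88% at 3-fold and 90% at 4-fold, with 2 false calls among 14649 unchanged genes. On the left the shares were 0, 50, 86 and 88% with 5 false calls. For pMC against control they were 14, 36, 88 and 98% on the right and 14, 44, 84 and 94% on the left. For the difference between sides against control they were 0, 12, 64 and 66%, and against pMC 0, 10, 34 and 68%.

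Before the data were examined, the lists, the rule for named genes, the tests and these alternatives were fixed: DESeq2 1.42.0 (Wald test), scaling by relative log expression, upper-quartile scaling, no filter on low counts, a stricter filter (CPM of 1 in 3 libraries), robust dispersions, the sample number as a block, a fit of only the compared groups, leaving out each library in turn, and for lists camera with an estimated correlation and fry. Another 4 were added after the data had been seen: a correction of each library for transcript length and GC content by natural splines (5 degrees of freedom each), a fit without the 3 libraries that stood apart from their groups, a fit with the skeletal muscle score as a covariate, and the correction and the removal of the 3 libraries together. Those 3 libraries were, in the 3 groups with the lowest correlations between libraries, the library with the lowest mean correlation with its group. All columns of the files were used.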

Results

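Bulk RNA sequencing was run on MO4 tumours, a mouse melanoma line derived from B16F10 that carries ovalbumin, grown under the skin of both hindlimbs of C57BL/6 mice. Cells made from induced pluripotent stem cells (pMC), or such cells marked IFN-alpha (IFN-alpha-pMC), had been placed beside the right tumour on days 5, 6 and 7, and the tumours were taken on day 11. Right tumours lay on the injected side, and left tumours were the distant ones. Each of the 6 groups (control, pMC and IFN-alpha-pMC on each side) held 3 libraries. The comparisons ask what changed beside the injected cells, what changed in the distant tumour, and what the IFN-alpha mark added to the cells alone. Fold changes are log2 values ± SE, and levels are mean CPM ± SD over 3 libraries. The p-values of genes are adjusted values of edgeR's quasi-likelihood test. Between 17844 and 18970 gene IDs per library had counts.

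The IFN-alpha-pMC libraries of both sides stood apart from the other 12 on the first principal component of the 1000 most variable genes, which held 65.2% of their variance (scores of 19.4 to 59.6 against -38.3 to -2.4). Within the control and IFN-alpha-pMC groups of each side, these scores had the same order as the skeletal muscle scores given below. Libraries 1, 2 and 3 were at -2.4, -33.9 and -8.3 in right controls and at -9.9, -38.3 and -29.4 in left controls. Treatment and muscle content are thus not told apart on this component. Spearman correlations between libraries of a group were 0.99 to 0.996 in left controls, 0.986 to 0.992 in right pMC and 0.993 to 0.995 in left pMC. They were lower in right controls (0.936 to 0.981), right IFN-alpha-pMC (0.962 to 0.994) and left IFN-alpha-pMC (0.964 to 0.995). Within these 3 groups the libraries with the lowest mean correlation with their own group were right control 3, right IFN-alpha-pMC 3 and left IFN-alpha-pMC 1 (0.9454, 0.9629 and 0.9678). Right control 2 was at 0.9584. Read pairs in no annotated feature separated every IFN-alpha-pMC library (4.04 to 6.12%) from every other library (6.87 to 12.21%). What lies behind this was not tested, and it cannot be told apart from treatment in comparisons of IFN-alpha-pMC with control or pMC. Their share moved with treatment on both sides. It was 4.84 ± 1% in right and 4.88 ± 1.08% in left IFN-alpha-pMC, against 9.35 ± 2.69% and 9.04 ± 1.28% in the controls and 7.43 ± 0.39% and 7.93 ± 0.73% with pMC.

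**Figure D1:**
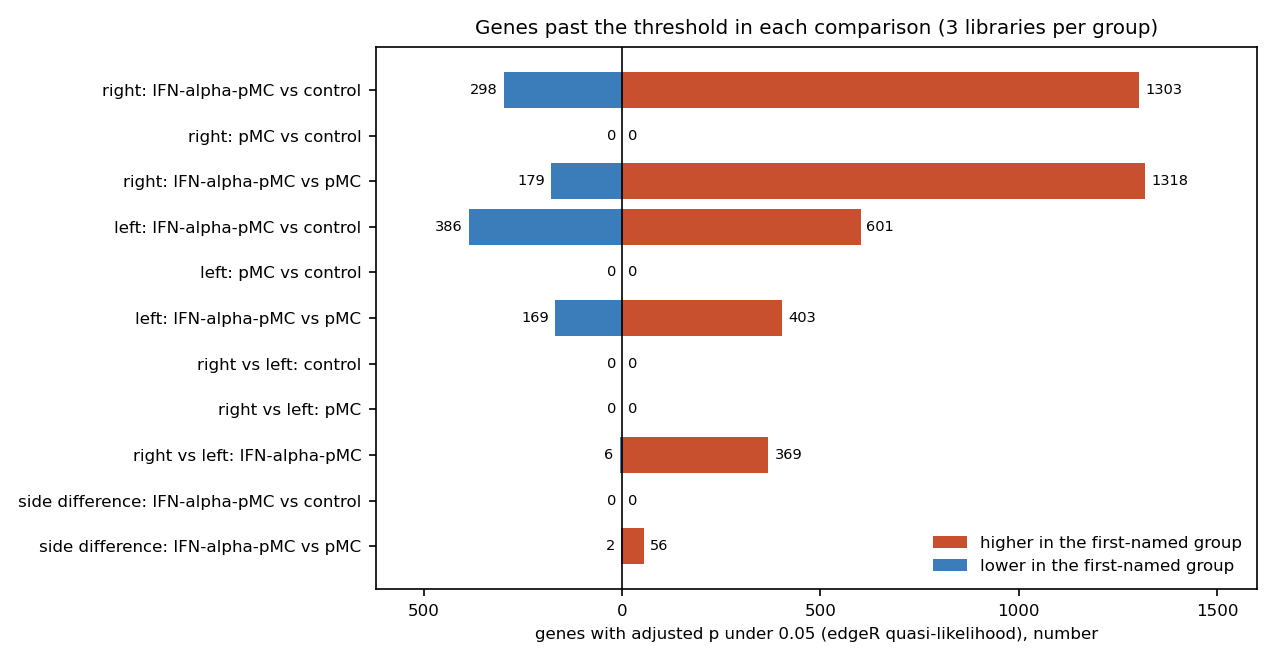
Number of genes with an adjusted p under 0.05 (edgeR quasi-likelihood, horizontal axis) in each of 11 comparisons of groups of 3 libraries, with genes higher in the first-named group to the right of 0 and lower genes to the left. IFN-alpha-pMC against control gave 1601 genes on the right and 987 on the left, and pMC against control gave 0 on both sides.

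Beside injected IFN-alpha-pMC, genes of killer lymphocytes were among the largest rises against control tumours of the same side. Gzmc (ENSMUSG00000079186), a granzyme of cytotoxic lymphocytes, had 633 counts over 3 libraries against 2 in controls (ratio 297, 95% interval 81.9 to 2460, adjusted p = 1.45e-06). Gzmb (ENSMUSG00000015437) rose from 3.28 ± 2.69 to 159 ± 24.4 CPM (5.63 ± 0.46, adjusted p = 2.76e-06) and Gzma (ENSMUSG00000023132) from 3.24 ± 2.36 to 158 ± 68.7 CPM (5.64 ± 0.51, adjusted p = 4.96e-06). Ly6c2 (ENSMUSG00000022584), a marker of inflammatory monocytes, rose from 10.7 ± 5.52 to 177 ± 9.61 CPM (4.06 ± 0.31, adjusted p = 1.54e-06). Genes of muscle fibres also rose. Ky had 89 counts against 0 (at least 27.8-fold, adjusted p = 0.000441), Lrrc30 had 73 against 1 (ratio 68.5, interval 11.9 to 2740) and Mylk4 rose by 5.48 ± 0.86. Genes of red blood cells were among the largest falls. Hba-a2 fell from 12.2 ± 8.88 to 1.64 ± 0.695 CPM (-2.91 ± 0.51, adjusted p = 0.000877). Alas2, the first enzyme of haem synthesis in erythroid cells, stood at -2.47 ± 0.53 and Hbb-bt at -2.94 ± 0.75 (adjusted p = 0.0731 without right IFN-alpha-pMC 1). Of 14849 genes tested, 1303 were higher and 298 lower.

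Interferon response genes rose together on this side. Of the type I interferon response list, 30 of 40 genes rose, 36 adjusted over the list alone. The median was 0.96 (camera adjusted p = 9.58e-25, adjusted p = 0.013 with an estimated correlation). Irf7, the transcription factor that amplifies interferon production, rose from 54.6 ± 13.5 to 244 ± 3.31 CPM (2.16 ± 0.18). Mx1, an antiviral GTPase, rose by 1.93 ± 0.21, Isg20, an exonuclease, by 2.12 ± 0.24 and Zbp1, a sensor of viral nucleic acid, by 1.69 ± 0.2. Of the interferon-gamma response list 26 of 27 rose, 26 adjusted over the list alone. The median was 1.51 (camera adjusted p = 4.04e-25, adjusted p = 0.0155 with an estimated correlation). Among them were Nos2 (2.82 ± 0.36), Gbp3 (1.4 ± 0.18) and the chemokines that draw T cells, Cxcl10 (137 ± 26.9 to 499 ± 57.7 CPM) and Cxcl9 (102 ± 31.2 to 272 ± 38 CPM). Antigen presentation moved the same way. Of the class I list 11 of 18 genes rose, 13 adjusted over the list alone. The median was 0.86 (camera adjusted p = 2.93e-09, adjusted p = 0.0187 with an estimated correlation), with H2-D1 at 2360 ± 238 against 971 ± 216 CPM and H2-T23 at 251 ± 48.2 against 59.8 ± 27 CPM. Class II genes rose in 8 of 13 cases, 12 adjusted over the list alone. The median was 1.32 (camera adjusted p = 3.38e-10, adjusted p = 0.038 with an estimated correlation), with the invariant chain Cd74 up by 1.56 ± 0.28 and the protease Ctss by 2.03 ± 0.24. The call of Isg15 (1.3 ± 0.33) ended without right control 1 (adjusted p = 0.104).

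Lymphocyte genes showed the largest list medians of this comparison. Of the T cell markers, 26 of 27 rose, 27 adjusted over the list alone. The median was 2.9 (camera adjusted p = 6.99e-34, adjusted p = 0.013 with an estimated correlation). Cd3g, a chain of the T cell receptor complex, went from 2.8 ± 0.724 to 30.4 ± 5.86 CPM (3.44 ± 0.3), Cd8b1 from 2.47 ± 1.06 to 24.1 ± 2.31 CPM (3.28 ± 0.34) and the costimulatory receptor Cd28 from 1.56 ± 0.436 to 14.3 ± 2.31 CPM (3.19 ± 0.33). Among cytotoxic effector genes 20 of 22 rose, 21 adjusted over the list alone. The median was 3.22 (camera adjusted p = 1.88e-30, adjusted p = 0.013 with an estimated correlation). Perforin, Prf1, rose from 1.65 ± 0.922 to 32.7 ± 6.86 CPM (4.3 ± 0.37), Ifng from 0.674 ± 0.515 to 7.1 ± 0.947 CPM (3.35 ± 0.4) and the chemokine Ccl5 from 21.7 ± 5.46 to 107 ± 18.4 CPM (2.31 ± 0.19). NK cell markers rose in 17 of 19 cases, 18 adjusted over the list alone. The median was 2.93 (camera adjusted p = 2.34e-20, adjusted p = 0.0249 with an estimated correlation), with Il2rb up by 2.84 ± 0.35 and Ncr1 by 2.61 ± 0.39. Checkpoint and regulatory genes rose in 14 of 17 cases, 15 adjusted over the list alone. The median was 2.02 (camera adjusted p = 1.41e-15, adjusted p = 0.013 with an estimated correlation). Cd274, which encodes PD-L1, went from 66.6 ± 27.3 to 236 ± 8.32 CPM (1.82 ± 0.27). Lag3 rose by 2.19 ± 0.25 and Pdcd1 by 2.26 ± 0.52, while Foxp3, the regulatory T cell factor, was at 1.1 ± 0.55 (adjusted p = 0.235). B and plasma cell genes rose in 6 of 12 cases, 10 adjusted over the list alone (median 1.27, camera adjusted p = 1.57e-05, adjusted p = 0.0223 with an estimated correlation), led by the immunoglobulin light chain Igkc (2.03 ± 0.39). The lymphoid chemokine and structure list rose in 7 of 11 cases, 8 adjusted over the list alone. The median was 1.52 (camera adjusted p = 6.35e-09, adjusted p = 0.013 with an estimated correlation).

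Myeloid genes rose as well. Monocyte and macrophage markers rose in 17 of 28 cases, 19 higher and 1 lower adjusted over the list alone. The median was 1.39 (camera adjusted p = 2.75e-14, adjusted p = 0.0249 with an estimated correlation), with the monocyte chemokine Ccl7 up from 10.6 ± 6.83 to 104 ± 39.7 CPM and Cd68 from 46.7 ± 8.55 to 163 ± 13 CPM. Of the neutrophil list 6 of 10 rose, 7 adjusted over the list alone. The median was 2.32 (camera adjusted p = 2.74e-06, adjusted p = 0.038 with an estimated correlation). Of the alternative macrophage activation list 6 of 14 rose, 7 adjusted over the list alone. The median was 1.4 (camera adjusted p = 0.000422, adjusted p = 0.039 with an estimated correlation). Arginase, Arg1, went from 2.01 ± 2.87 to 68.5 ± 51.4 CPM (5.18 ± 0.93) and Chil3 rose by 3.94 ± 0.57. In the dendritic cell lists 6 of 19 XCR1+ conventional, 7 of 18 activated and 5 of 12 plasmacytoid genes rose (8, 10 and 9 adjusted over the list alone). Their medians were 0.73, 0.97 and 1.4 (camera adjusted p = 3.33e-06, 9.11e-06 and 6.42e-06, adjusted p = 0.026, 0.026 and 0.0155 with an estimated correlation). Within the first of these Irf8 rose by 1.84 ± 0.21 and Ifi205 by 2.87 ± 0.32, while Xcr1 (0.73 ± 0.33, adjusted p = 0.177) and Clec9a (0.77 ± 0.35, adjusted p = 0.193) did not pass. Of 7 mast cell and basophil genes 3 rose and 1 fell, 4 and 1 adjusted over the list alone (median 1.64, camera adjusted p = 0.0056, adjusted p = 0.107 with an estimated correlation), led by the histamine-forming enzyme Hdc (2.14 ± 0.31), which is also on the neutrophil list.

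Genes of the melanocyte lineage did not pass. On that list 0 of 22 genes passed by edgeR, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 with DESeq2 (median 0.02, camera adjusted p = 0.877). Tyrosinase, Tyr, was at 2060 ± 533 against 2090 ± 841 CPM and Mlana at 0.24 ± 0.35. Of 29 proliferation genes edgeR called 0, 0 adjusted over the list alone, with 3 lower at an unadjusted p under 0.05 and 1 lower with DESeq2. The median was -0.2 (camera adjusted p = 0.00204, adjusted p = 0.252 with an estimated correlation), and Mki67 was at 132 ± 100 against 319 ± 155 CPM (-1.28 ± 0.42, adjusted p = 0.0603). Of 20 endothelial genes 4 fell, 5 adjusted over the list alone. The median was -0.6 (camera adjusted p = 0.000466, adjusted p = 0.257 with an estimated correlation). Aplnr was at -1.22 ± 0.31 (adjusted p = 0.103 without right control 1) and Ptprb at -1.2 ± 0.35 (adjusted p = 0.157 without right IFN-alpha-pMC 2). Of 28 fibroblast and matrix genes 6 rose, 6 adjusted over the list alone. The median was 0.71 (camera adjusted p = 2.66e-05, adjusted p = 0.257 with an estimated correlation). They include Thy1 (2.28 ± 0.22), which T cells also carry, and the collagenase Mmp13 (2.97 ± 0.35). Skeletal muscle genes rose in 7 of 24 cases, 10 adjusted over the list alone. The median was 2.55 (camera adjusted p = 2.82e-11, adjusted p = 0.129 with an estimated correlation), with Casq1 up from 6.19 ± 4.47 to 64.4 ± 23.9 CPM, while Ckm was at 188 ± 41.1 against 30.9 ± 36 CPM (adjusted p = 0.143). Muscle scores were 2.41, 2.7 and 3.66 in these libraries and 1.96, -2.36 and -0.66 in right controls. Of 8 erythroid genes 5 fell, 5 adjusted over the list alone. The median was -2.23 (camera adjusted p = 0.00268, adjusted p = 0.257 with an estimated correlation, and camera adjusted p = 0.169 without right IFN-alpha-pMC 3 and 0.0686 without right control 3).

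Of the genes that respond to tissue handling 7 of 20 rose, 9 adjusted over the list alone. The median was 0.71 (camera adjusted p = 3.33e-06, adjusted p = 0.0865 with an estimated correlation). The stress factor Atf3 rose by 2.08 ± 0.26 and Junb by 1.18 ± 0.17. Of the hypoxia and glycolysis list 3 of 22 rose, 3 adjusted over the list alone. The median was 0.38 (camera adjusted p = 0.00118, adjusted p = 0.216 with an estimated correlation). Of the apoptosis and p53 targets 3 of 18 rose, 3 adjusted over the list alone. The median was 0.34 (camera adjusted p = 0.00467, adjusted p = 0.107 with an estimated correlation), with the cell cycle inhibitor Cdkn1a up by 1.06 ± 0.21. Of 8 adipocyte genes 3 rose and 1 fell, the same numbers as adjusted over the list alone (median 0.07, camera adjusted p = 0.372). Pparg was at 1.37 ± 0.22 and Scd1 at -1.03 ± 0.23. Of 10 pluripotency and embryonic blood genes 1 rose and 1 fell, 2 and 1 adjusted over the list alone (median -0.13, mean 0.09, camera adjusted p = 0.748). Myb was at 1.44 ± 0.37 (adjusted p = 0.0851 without right IFN-alpha-pMC 2) and Gata2 at -0.83 ± 0.23 (adjusted p = 0.149 without the same library), both also blood cell factors. Pou5f1 and Sox2 had 0 counts. Of 4 keratinocyte genes 0 passed with edgeR, at an unadjusted p under 0.05 or with DESeq2 (median -0.25). The female-specific Xist, the 1 tested gene of the sex check, was at 0.18 ± 0.33 with 0 counts of Ddx3y, Kdm5d and Eif2s3y.

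Of 112 named genes past the threshold, 82 stayed past it with each library left out, 109 with a correction for transcript length and GC content and 87 with the muscle score as a covariate. That score comes from the same counts and was higher in every IFN-alpha-pMC library than in every control library of its side. Calls lost with the covariate, here and below, can therefore reflect muscle content or lost power, which the fit does not tell apart. The total of 1601 (81.4% higher) became 3946 (1962 higher, 1984 lower) without right control 3, 3105 (1272 higher, 1833 lower) without right IFN-alpha-pMC 3 and 8175 without the 3 libraries that stood apart (4261 higher). It was 970 with the muscle covariate, 582 in a fit of the compared groups alone and 2076 with DESeq2 (70.9% higher). With the length and GC correction it was 2398 (67.3% higher). Without the 3 libraries, Spearman correlations of centred log2 CPM with transcript length were 0.33 and 0.55 in right controls and -0.29 and -0.41 in right IFN-alpha-pMC. A length trend thus goes with treatment in that fit, and with the correction as well its count was 6559 (3256 higher).

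**Figure D2:**
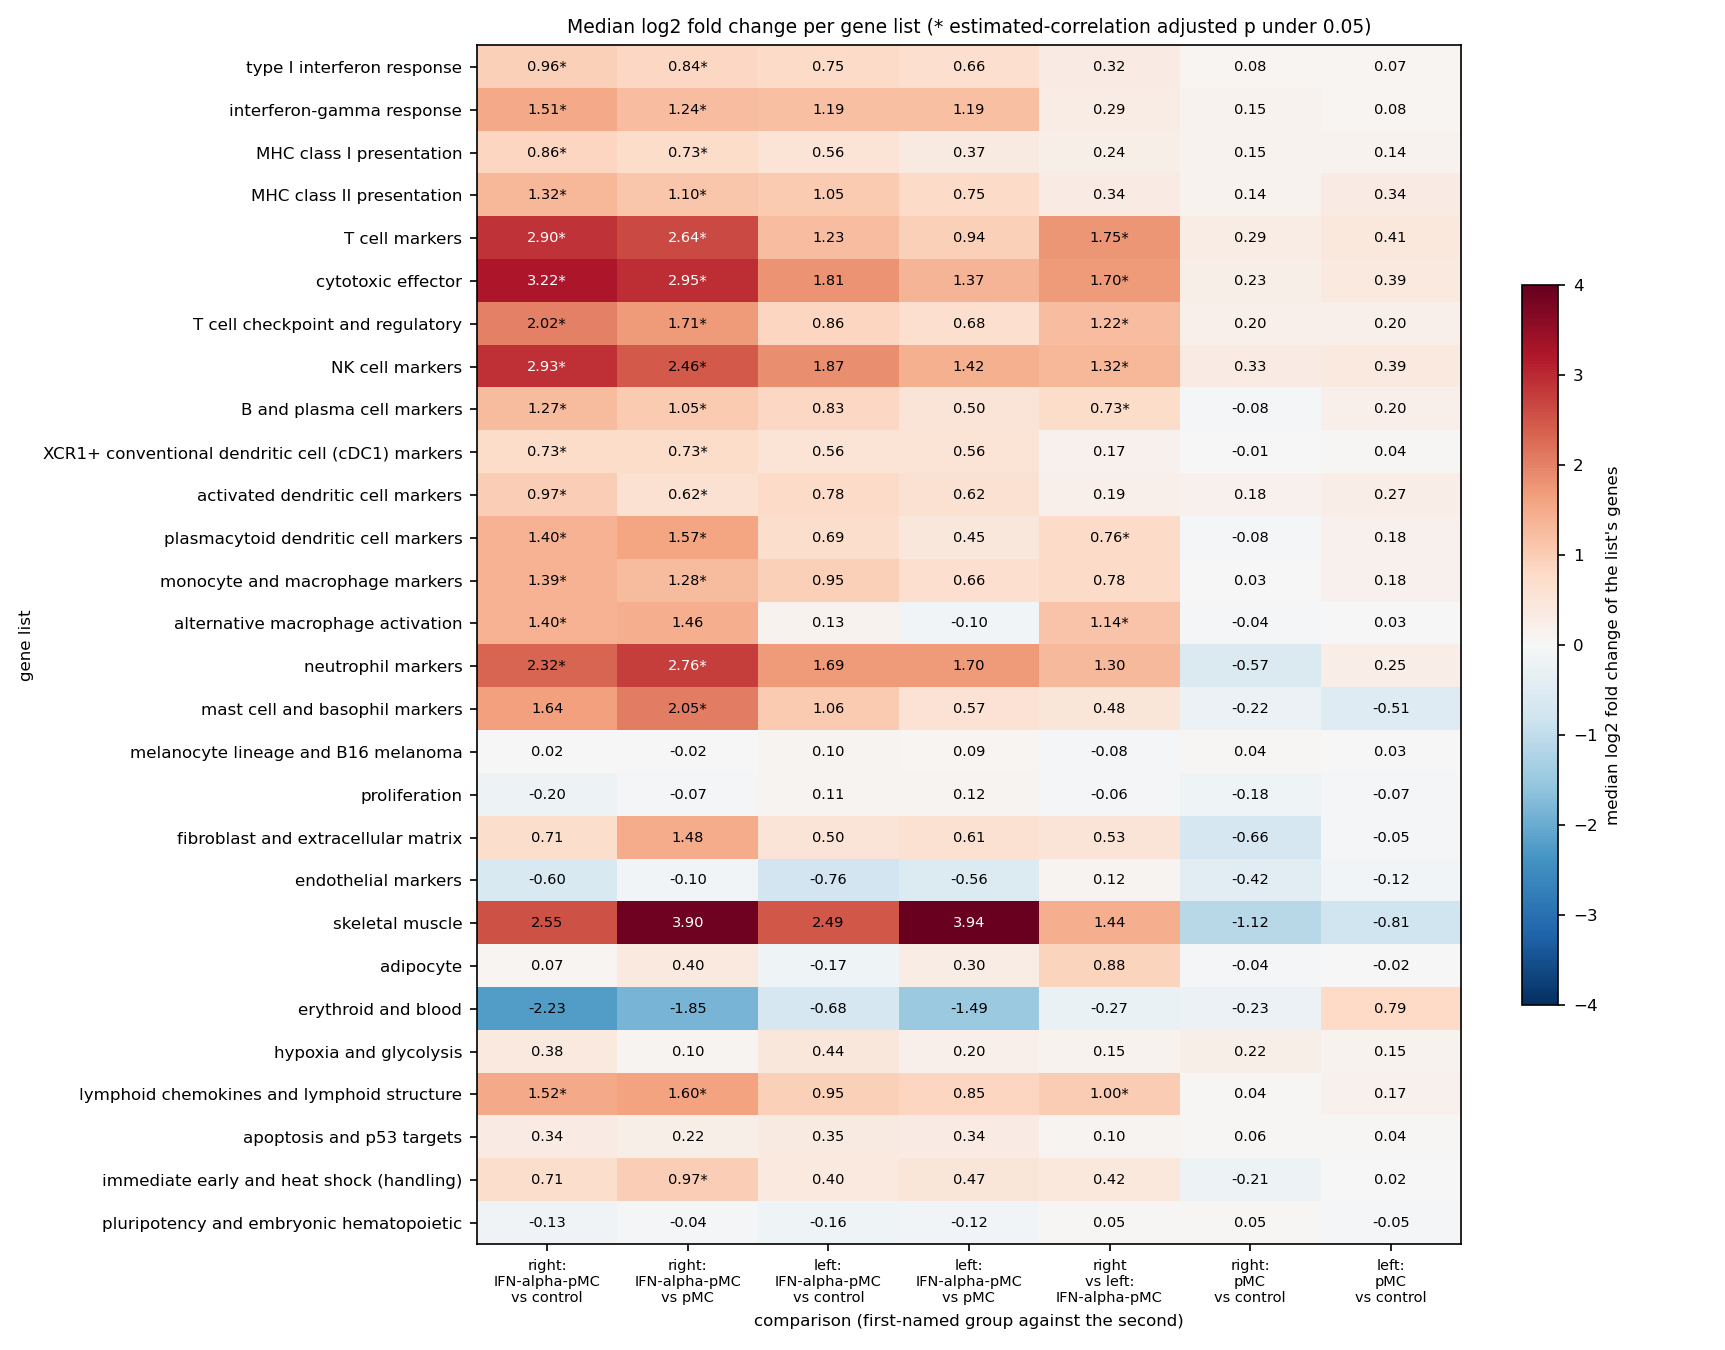
Median log2 fold change of the tested genes of 28 lists (rows) in 7 comparisons (columns), on a colour scale from -4 (blue) to 4 (red), with a star where the camera test with an estimated correlation had an adjusted p under 0.05. T cell markers ranged from 2.9 for IFN-alpha-pMC against control on the right to 0.29 for pMC against control on the right, and the melanocyte list from -0.08 to 0.1.

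Against pMC, the cells without the IFN-alpha mark, the right IFN-alpha-pMC tumours showed the same kinds of genes at the top. Gzmc was at 10.4 ± 3.53 against 0.106 ± 0.056 CPM (6.55 ± 0.51, adjusted p = 2.07e-06), Gzmd, a related granzyme, had 100 counts against 1 (ratio 93.3, interval 16.4 to 3720). Tarm1, an activating receptor of myeloid cells, had 122 against 1 (ratio 114, interval 20.1 to 4530). Arg1 rose by 5.8 ± 0.96, and the muscle genes Cacng6 (80 counts against 1, ratio 74.7, interval 13 to 2990) and Lrrc30 (73 against 1, ratio 68.1, interval 11.9 to 2730) followed. With the muscle covariate the calls of Gzmd, Cacng6 and Lrrc30 ended (adjusted p = 0.147, 0.861 and 0.0751). The covariate is made of muscle genes, so a weaker call of muscle genes such as Cacng6 and Lrrc30 is built into this fit. Among the 6 largest falls, the clock gene Per1 went from 117 ± 16.4 to 30.4 ± 11.8 CPM (-1.94 ± 0.42, adjusted p = 0.149 with the muscle covariate). The globins Hba-a2 (-2.06 ± 0.5) and Hba-a1 (-2.03 ± 0.53) fell as well, with adjusted p = 0.0515 and 0.105 without right pMC 3. Of the genes tested 1318 were higher and 179 lower.

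T cell markers rose in 26 of 27 cases, 27 adjusted over the list alone. The median was 2.64 (camera adjusted p = 5.94e-34, adjusted p = 0.0154 with an estimated correlation), with Cd3g up from 3.56 ± 0.861 to 30.4 ± 5.86 CPM (3.09 ± 0.29) and Cd8a by 2.48 ± 0.38. Cytotoxic effector genes rose in 20 of 22 cases, 20 adjusted over the list alone. The median was 2.95 (adjusted p = 0.0154 with an estimated correlation). Gzmb rose by 4.74 ± 0.43, Prf1 by 3.97 ± 0.36 and Ifng by 3.12 ± 0.4. Interferon genes rose in 27 of 40 type I and 23 of 27 interferon-gamma response cases, 32 and 26 adjusted over the lists alone (medians 0.84 and 1.24, adjusted p = 0.0154 and 0.0222 with an estimated correlation). Irf7 went from 57.9 ± 3.05 to 244 ± 3.31 CPM and Cxcl10 from 136 ± 28.5 to 499 ± 57.7 CPM. NK genes rose in 17 of 19, monocyte and macrophage genes in 17 of 28 and neutrophil genes in 9 of 10 cases, 18, 20 and 10 adjusted over the lists alone (adjusted p = 0.0248, 0.0248 and 0.0231 with an estimated correlation). Muscle genes rose in 15 of 24 cases, 21 adjusted over the list alone. The median was 3.9 (camera adjusted p = 2.4e-13, adjusted p = 0.0949 with an estimated correlation). Fibroblast genes rose in 13 of 28, 16 adjusted over the list alone (median 1.48, camera adjusted p = 2.01e-11, adjusted p = 0.0885 with an estimated correlation), and Dcn rose by 2.74 ± 0.41. Handling genes rose in 9 of 20, 11 adjusted over the list alone. The median was 0.97 (adjusted p = 0.034 with an estimated correlation). Of 22 melanocyte genes 0 passed by edgeR (2 at an unadjusted p under 0.05, 0 with DESeq2, median -0.02). The total of 1497 (88% higher) was 754 with the muscle covariate, 2569 with the length and GC correction (64.1% higher) and 4287 without the 3 libraries that stood apart (1871 higher). Of 109 named genes past the threshold, 86 stayed past it with each library left out and 79 with the muscle covariate.

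The cells without the mark left no gene past the threshold in right tumours. Against control, edgeR called 0 genes (359 at an unadjusted p under 0.05, smallest adjusted p 0.945) and DESeq2 called 2, both lower. Those 359 were 2.4% of the genes tested, below the share of 0.05 that a calibrated test gives without any change. The test thus appears conservative here, and 0 calls do not show that nothing changed. Irf7 was at 0.09 ± 0.18, Cxcl9 at 0 ± 0.23, Cd8a at 0.32 ± 0.38, Gzmb at 0.89 ± 0.41 and Tyr at 0.52 ± 0.29. No member of any list passed over all genes with edgeR or DESeq2. The fibroblast list stood lower (median -0.66, camera adjusted p = 6.25e-08, adjusted p = 0.58 with an estimated correlation), as did the endothelial list (median -0.42, camera adjusted p = 2.59e-06, adjusted p = 0.58 with an estimated correlation, 1 gene lower adjusted over the list alone). Camera's adjusted p was 0.0527 for fibroblast genes without right control 3 and 0.283 for endothelial genes without right control 1. T cell markers had a median of 0.29 (camera adjusted p = 0.00381, adjusted p = 0.626 with an estimated correlation). It was -0.11 without right control 1 (camera adjusted p = 0.995), 0.25 without right control 3 (0.0603), and 0.07 and 0.14 without right pMC 2 and 3 (0.0857 and 0.105). Without the 3 libraries that stood apart the comparison called 5067 genes (2932 higher, 2135 lower), and without right control 3 it called 1. The other removed libraries were of IFN-alpha-pMC, outside this comparison. The step from 1 to 5067 thus came through what all groups share in the fit, such as the spread. In the libraries kept, Spearman correlations of centred log2 CPM with transcript length were 0.33 and 0.55 in right controls and -0.13 to 0.04 in right pMC. A length trend thus runs along this comparison, and the 5067 genes are not read as an effect of the cells.

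**Figure D3:**
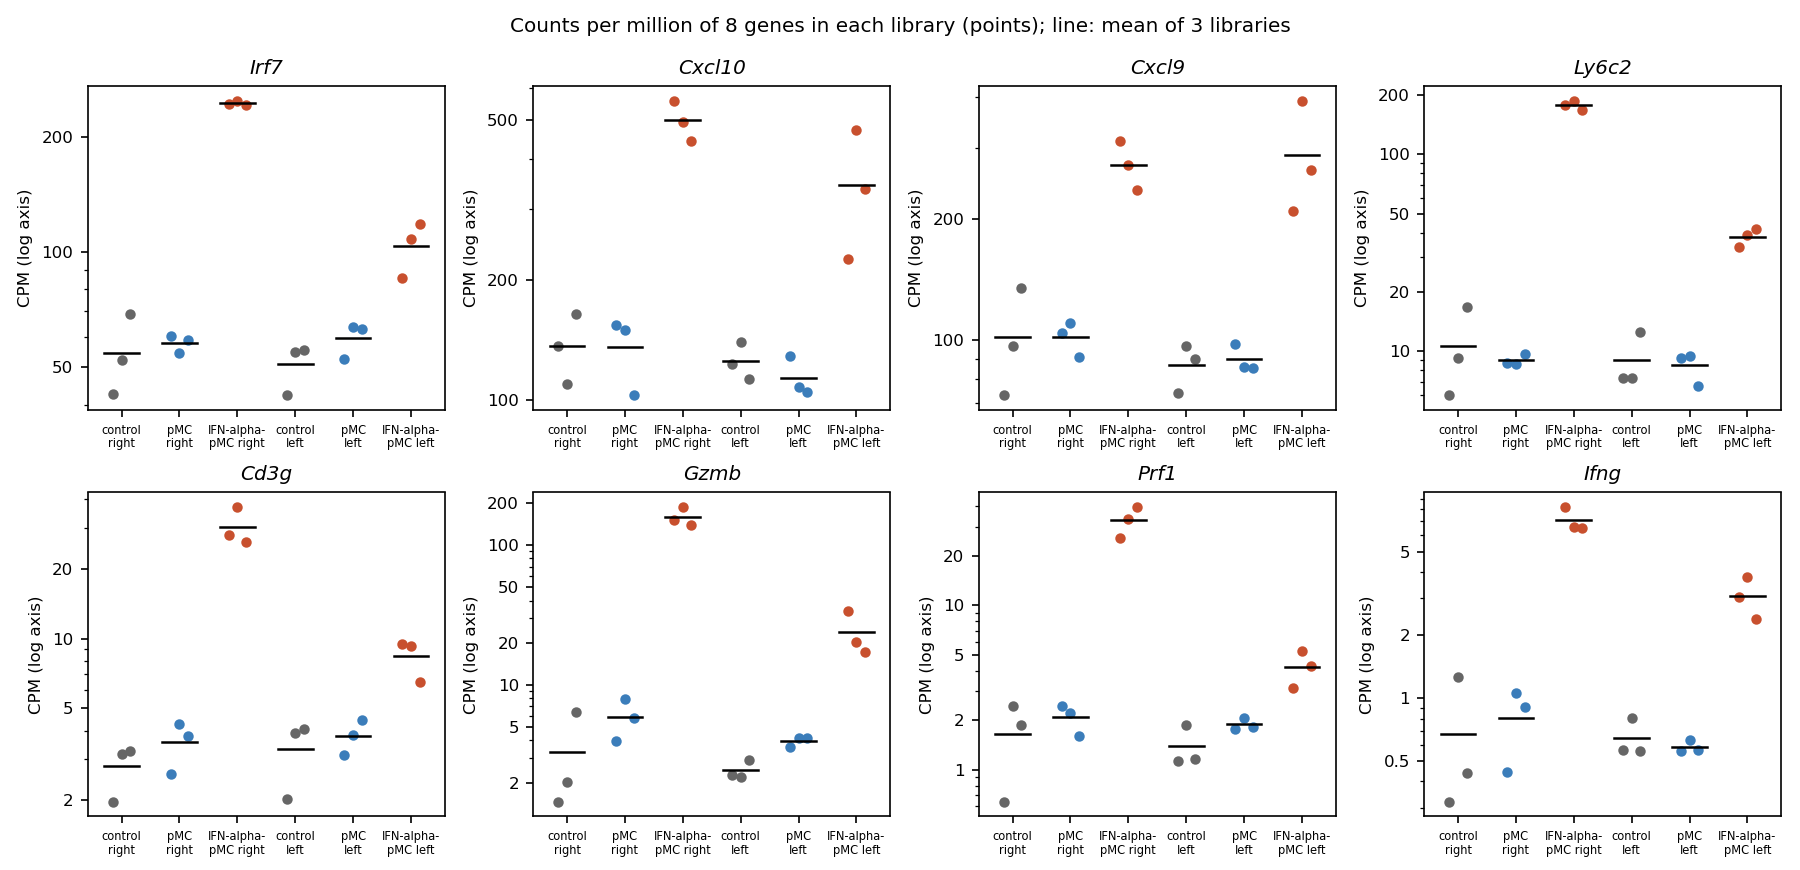
CPM on a log axis of 8 genes in each of the 18 libraries (points) with the mean of each group (line). Right IFN-alpha-pMC libraries lay above all control and pMC libraries for each gene, for example Prf1 with a mean of 32.7 CPM against 1.65 in right controls, and left IFN-alpha-pMC means lay between or, for Cxcl9 (288 against 272 CPM), at the level of the right.

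In the distant left tumours of IFN-alpha-pMC mice, interferon response genes and cytotoxic genes were higher than in left controls. Cxcl9, the T cell chemokine that interferon-gamma induces, rose from 86.7 ± 11.7 to 288 ± 94.2 CPM (1.73 ± 0.24, adjusted p = 0.00187). The guanylate-binding gene Gbp2 rose from 318 ± 34.3 to 875 ± 182 CPM (1.46 ± 0.22) and the interferon-induced GTPase Iigp1 from 556 ± 113 to 1950 ± 332 CPM (1.81 ± 0.27). Zbp1 rose from 115 ± 16 to 314 ± 22.4 CPM (1.45 ± 0.2) and Isg20 by 1.67 ± 0.24. Gzmb rose from 2.46 ± 0.383 to 23.7 ± 8.8 CPM (3.26 ± 0.43, adjusted p = 0.00171), Ccl5 by 1.4 ± 0.19 and Ly6c2 from 9.07 ± 3.01 to 38.2 ± 4.18 CPM (2.07 ± 0.29). Of the falls, Msi1 went from 11.7 ± 3.76 to 2.62 ± 0.52 CPM (-2.16 ± 0.36). These genes, with Ifit1, Ifi44, Gbp3, Cxcl10, H2-DMa, Gzma, Ccl4, Cd24a, Ifi205, Ccl7 and Atf3, are among the 21 of 87 named genes that stayed past the threshold with each library left out. In all, 601 genes were higher and 386 lower.

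By lists, 23 of 40 type I interferon genes rose, 31 adjusted over the list alone. The median was 0.75 (camera adjusted p = 1.05e-13, adjusted p = 0.182 with an estimated correlation). Of the interferon-gamma response list 20 of 27 rose, 26 adjusted over the list alone. The median was 1.19 (camera adjusted p = 2.23e-17, adjusted p = 0.182 with an estimated correlation). Cytotoxic effector genes rose in 15 of 22 cases, 19 adjusted over the list alone (median 1.81, or 1.74 with Gzmd at its lower bound, camera adjusted p = 5.43e-12, adjusted p = 0.182 with an estimated correlation). T cell markers rose in 12 of 27, 18 adjusted over the list alone. The median was 1.23 (camera adjusted p = 4.83e-08, adjusted p = 0.216 with an estimated correlation). Cd3g went from 3.33 ± 1.13 to 8.42 ± 1.69 CPM (adjusted p = 0.0182, and 0.0934 without left control 1) and Cd8a from 3.8 ± 1.23 to 10.2 ± 1.57 CPM (adjusted p = 0.042, and 0.153 without left control 1). Cd3e was at 0.66 ± 0.39 (adjusted p = 0.219). NK genes rose in 10 of 19 cases, 14 adjusted over the list alone. The median was 1.87 (adjusted p = 0.216 with an estimated correlation). Monocyte and macrophage genes rose in 13 of 28, 18 adjusted over the list alone. The median was 0.95 (adjusted p = 0.182 with an estimated correlation). Class I genes rose in 4 of 18 and class II genes in 6 of 13 cases, 11 and 12 adjusted over the lists alone (medians 0.56 and 1.05, adjusted p = 0.182 and 0.184 with an estimated correlation). Of the XCR1+ dendritic cell list 5 of 19 rose, 8 adjusted over the list alone. The median was 0.56 (adjusted p = 0.182 with an estimated correlation), with Xcr1 itself at 1.2 ± 0.34 (adjusted p = 0.046, and 0.16 without left control 1).

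Muscle genes moved with these groups too. Of 24, 6 rose, 14 adjusted over the list alone. The median was 2.49 (camera adjusted p = 9.52e-08, adjusted p = 0.276 with an estimated correlation). Mylpf went from 8.11 ± 9.84 to 225 ± 150 CPM (adjusted p = 0.0314, and 0.132 without left control 3) and Pvalb from 3.65 ± 4.24 to 128 ± 66.5 CPM (adjusted p = 0.0392, and 0.139 without the same library). Tceal7 had 281 counts against 2 (ratio 125, interval 34.2 to 1030, adjusted p = 0.0522 without left control 3). Muscle scores were 2.17, 1.81 and 1.14 in left IFN-alpha-pMC and 0.53, -3.63 and -2.01 in left controls. The endothelial list stood lower. The median was -0.76 (camera adjusted p = 0.000235, adjusted p = 0.296 with an estimated correlation), with 0 of 20 genes past the edgeR threshold, 12 lower at an unadjusted p under 0.05 and 4 lower with DESeq2. Of 22 melanocyte genes edgeR called 0 (4 higher and 3 lower at an unadjusted p under 0.05, 1 lower with DESeq2, median 0.1, camera adjusted p = 0.719), and Mki67 was at -1.16 ± 0.41 (adjusted p = 0.0742).

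The left total of 987 genes (60.9% higher) was lower without any 1 library: 119, 113 and 86 without left control 1, 2 and 3, and 394, 177 and 494 without left IFN-alpha-pMC 1, 2 and 3. It was 147 with the muscle covariate (26 of 87 named genes stayed past the threshold), 665 with the length and GC correction (73.1% higher, 64 of 87 named genes), 2823 with DESeq2 (50.1% higher), 3062 in a fit of the compared groups alone (1007 higher, 2055 lower) and 4331 without the 3 libraries that stood apart (1956 higher, 2375 lower). The last 2 fits thus turned the balance to lower genes. Across genes, left fold changes fell with transcript length (Spearman rho -0.42, against -0.21 on the right).

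Against left pMC, the left IFN-alpha-pMC tumours showed 403 genes higher and 169 lower. Cxcl9 rose from 89.6 ± 7.13 to 288 ± 94.2 CPM (1.69 ± 0.24, adjusted p = 0.00272), Cxcl10 by 1.59 ± 0.24, Zbp1 by 1.38 ± 0.2 and Iigp1 by 1.73 ± 0.27. Gzmb rose from 3.96 ± 0.308 to 23.7 ± 8.8 CPM (2.58 ± 0.41, adjusted p = 0.0053) and Ly6c2 by 2.17 ± 0.29. These, with Isg20, Gbp3, Cd24a and the muscle gene Yipf7 (60 counts against 0, at least 22.5-fold), are the 10 of 68 named genes past the threshold with each library left out. Gzmb was not past it with the muscle covariate (adjusted p = 0.0688), nor was Yipf7 (adjusted p = 0.098). Type I interferon genes rose in 15 of 40 and interferon-gamma response genes in 16 of 27 cases, 28 and 26 adjusted over the lists alone (medians 0.66 and 1.19, adjusted p = 0.21 for both with an estimated correlation). Cytotoxic genes rose in 10 of 22 cases, 17 adjusted over the list alone. The median was 1.37 (adjusted p = 0.21 with an estimated correlation). T cell markers rose in 4 of 27, 8 adjusted over the list alone. The median was 0.94 (adjusted p = 0.305 with an estimated correlation), with Cd8a at 0.98 ± 0.37 (adjusted p = 0.103). Muscle genes rose in 6 of 24 cases, 18 adjusted over the list alone. The median was 3.94 (adjusted p = 0.253 with an estimated correlation). The total of 572 (70.5% higher) was 46, 38 and 34 without left pMC 1, 2 and 3 and 33 and 233 without left IFN-alpha-pMC 2 and 3. It was 95 with the muscle covariate, 1984 with DESeq2 (61.1% higher), 2538 in a fit of the compared groups alone (950 higher, 1588 lower) and 4142 without the 3 libraries that stood apart (1900 higher, 2242 lower), so the balance turned to lower genes in the last 2.

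The distant tumours of pMC mice gave 0 genes against left controls by edgeR (119 at an unadjusted p under 0.05, smallest adjusted p 1) and 1 by DESeq2. Those 119 were 0.8% of the genes tested, below the share of 0.05 that a calibrated test gives without any change. The spread came from all 6 groups, and libraries differed more within the right control and IFN-alpha-pMC groups. The test thus appears conservative here, and 0 calls do not show that nothing changed. Irf7 was at 0.23 ± 0.18, Cxcl9 at 0.05 ± 0.23, Gzmb at 0.68 ± 0.43 and Cd8a at 0.44 ± 0.38. T cell markers had a median of 0.41 (camera adjusted p = 2.04e-05, adjusted p = 0.541 with an estimated correlation). Cytotoxic genes had one of 0.39, or 0.37 with Gzmd at its bound (camera adjusted p = 0.000162, adjusted p = 0.541 with an estimated correlation), and erythroid genes of 0.79 (camera adjusted p = 0.000162, adjusted p = 0.541 with an estimated correlation). Without left control 1 camera's adjusted p was 0.066 for both T cell and cytotoxic genes. By edgeR 0 members of these lists passed over all genes or adjusted over the list alone.

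The genes that IFN-alpha-pMC changed against control overlapped between sides. The sides share no libraries, but their samples may come from the same mice, which the labels do not say. Both sides were fitted in the same model. On both, muscle scores were higher with IFN-alpha-pMC and fold changes against control fell with transcript length. The numbers for independent lists below are therefore a reference and not a test, and the overlap is not an independent replication. Of the 601 genes higher on the left, 441 (73.4%) were also higher on the right, against 52.7 for independent lists, and of the 386 lower on the left 102 (26.4%) were lower on the right, against 7.7. No gene passed in opposite directions, and the right fold change had the same sign for 595 of 601 and 385 of 386. Against pMC, 311 of 403 higher genes (77.2%) and 26 of 169 lower genes (15.4%) were shared, against 35.8 and 2 for independent lists.

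Within IFN-alpha-pMC mice, lymphocyte genes were higher on the injected side than on the distant side. Prf1 was at 32.7 ± 6.86 against 4.23 ± 1.06 CPM (2.94 ± 0.34, adjusted p = 0.000788) and Gzmb at 159 ± 24.4 against 23.7 ± 8.8 CPM (2.74 ± 0.39). Gzmc was at 10.4 ± 3.53 against 0.498 ± 0.242 CPM (4.43 ± 0.43), Cd3g at 30.4 ± 5.86 against 8.42 ± 1.69 CPM (1.85 ± 0.27) and Ly6c2 at 177 ± 9.61 against 38.2 ± 4.18 CPM (2.21 ± 0.29). Irf7 was higher by 1.23 ± 0.18 and Klrg1, a receptor of differentiated killer cells, by 3.11 ± 0.53. Cxcl9 was at -0.08 ± 0.23 (adjusted p = 0.904), Cxcl10 at 0.53 ± 0.23 (adjusted p = 0.377), Ifit1 at 0.19 ± 0.18 (adjusted p = 0.694) and Isg15 at -0.01 ± 0.33 (adjusted p = 0.995), so these 4 did not pass. T cell markers were higher on the right in 21 of 27 cases, 24 adjusted over the list alone. The median was 1.75 (camera adjusted p = 1.77e-40, adjusted p = 0.0128 with an estimated correlation). Cytotoxic genes were higher in 14 of 22, 19 adjusted over the list alone. The median was 1.7 (adjusted p = 0.0128 with an estimated correlation). NK genes passed in 5 of 19 and checkpoint genes in 6 of 17 cases, 14 and 11 adjusted over the lists alone (medians 1.32 and 1.22, adjusted p = 0.0456 and 0.0229 with an estimated correlation). Only 3 of 40 type I and 2 of 27 interferon-gamma response genes passed, 11 and 2 adjusted over the lists alone (medians 0.32 and 0.29, camera adjusted p = 9.32e-10 and 7.76e-05, adjusted p = 0.0954 and 0.31 with an estimated correlation). Muscle genes passed in 2 of 24 cases, 2 adjusted over the list alone. The median was 1.44 (adjusted p = 0.349 with an estimated correlation).

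In this comparison 369 genes were higher and 6 lower on the right. Among the lower were Enpp6, Rgs4, Rgs5, which marks pericytes, and Nsdhl, a sterol enzyme, between -1.08 and -0.68 (their highest adjusted p with a library left out was 0.0615, 0.128, 0.0753 and 0.063). The total of 375 was 222 and 155 without right IFN-alpha-pMC 2 and 3, 141, 159 and 233 without left IFN-alpha-pMC 1, 2 and 3. It was 566 with DESeq2, 190 in a fit of the compared groups alone and 863 without the 3 libraries that stood apart (430 higher, 433 lower). Of the named genes 26 of 59 named genes stayed past the threshold with each library left out.

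Without the IFN-alpha mark no single gene passed between right and left tumours. In control mice edgeR called 0 genes (116 at an unadjusted p under 0.05) and in pMC mice 0 (310 at an unadjusted p under 0.05), and DESeq2 called 0 in both. The 116 and 310 were 0.8% and 2.1% of the genes tested, also below a share of 0.05, so the test appears conservative here too. In controls 1 gene passed without the 3 libraries that stood apart. Irf7 was at 0.1 ± 0.18 and -0.04 ± 0.18 and Gzmb at 0.37 ± 0.44 and 0.58 ± 0.4. The muscle list had a median of 1.18 in control (camera adjusted p = 1.59e-11, adjusted p = 0.501 with an estimated correlation) and 1.2 in pMC mice (camera adjusted p = 1.51e-05, adjusted p = 0.997 with an estimated correlation), and Ckm was at 2.18 ± 1.09 in controls (adjusted p = 1). The muscle call ended without right control 1 (median -0.18, camera adjusted p = 0.896) or left control 2 (camera adjusted p = 0.0566), and in pMC mice without left pMC 1 (camera adjusted p = 0.256). Erythroid genes had a median of 1.52 in control mice, 4 of 8 adjusted over the list alone (camera adjusted p = 2.78e-09, adjusted p = 0.302 with an estimated correlation).

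**Figure D4:**
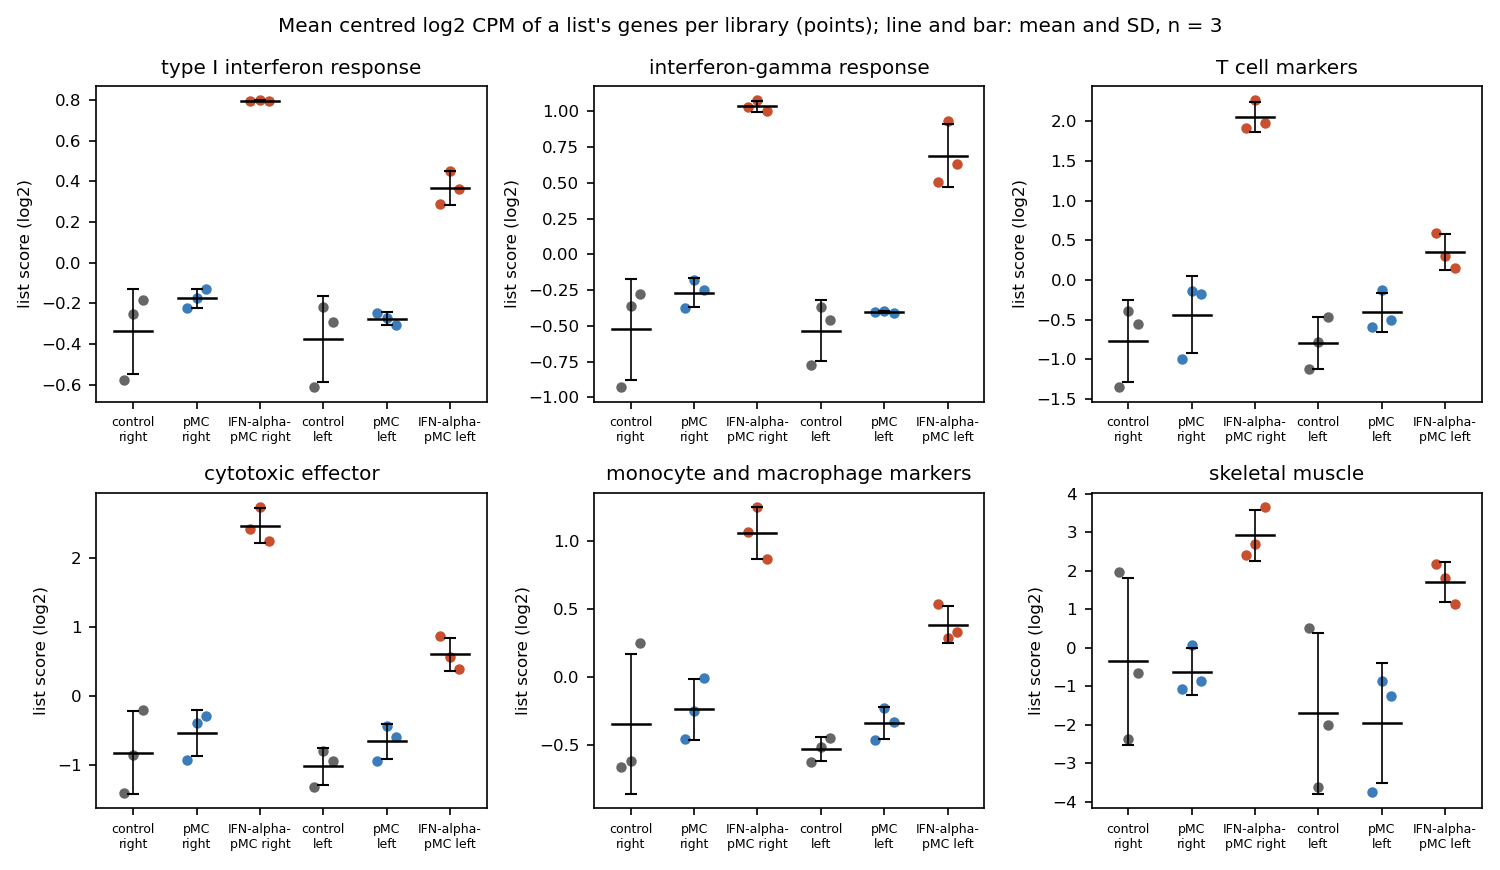
Scores of 6 lists (mean centred log2 CPM of the list's genes) in each of the 18 libraries (points), with the mean and SD of 3 libraries per group. T cell scores were 1.92 to 2.26 in right and 0.15 to 0.59 in left IFN-alpha-pMC libraries and at most -0.13 in all others, while muscle scores of control libraries ran from -3.63 to 1.96.

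The difference between sides was tested as the right effect minus the left effect. Relative to pMC, 58 genes passed, 56 with the larger rise on the right. T cell and killer cell genes were among them, with Gzma (3.19 ± 0.63), Prf1 (2.79 ± 0.49), the T cell receptor kinase Zap70 (2.7 ± 0.47), Cd28 (2.52 ± 0.45) and Cd8b1 (2.4 ± 0.46), with Ly6c2 (2.12 ± 0.4) and Irf7 (1.28 ± 0.25). Gzmb was at 2.17 ± 0.55 (adjusted p = 0.108) and Cxcl9 at -0.27 ± 0.33 (adjusted p = 0.69). T cell markers passed in 5 of 27 cases, 20 adjusted over the list alone (median 1.85, camera adjusted p = 6.06e-22, adjusted p = 0.084 with an estimated correlation), and interferon-gamma response genes in 0 of 27 by edgeR (3 higher and 1 lower at an unadjusted p under 0.05, 1 higher with DESeq2, median 0.2, camera adjusted p = 0.103). None of the 16 named genes past the threshold stayed past it with each library left out. Prf1 was at adjusted p = 0.0965 and Gzma at 0.134 without left pMC 2 and Zap70 at 0.089 without left pMC 3. Without left pMC 2, Cd28 was at adjusted p = 0.119, Cd8b1 at 0.127, Ly6c2 at 0.122 and Irf7 at 0.134. The total was 0 without right pMC 1 or 2, left pMC 2 or 3, right IFN-alpha-pMC 2 or 3, or left IFN-alpha-pMC 1 or 2, and 36 without left IFN-alpha-pMC 3. DESeq2 called 253 (80.6% higher, against 96.6%).

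Relative to control, edgeR called 0 genes for the difference between sides (918 at an unadjusted p under 0.05, smallest adjusted p 0.0581) and DESeq2 called 86. Prf1 was at 2.68 ± 0.5 (adjusted p = 0.0723), Irf7 at 1.13 ± 0.25 (adjusted p = 0.137) and Cxcl9 at -0.31 ± 0.33 (adjusted p = 0.801). T cell markers passed in 0 of 27 cases over all genes by edgeR, 8 with DESeq2, 22 at an unadjusted p under 0.05 and 21 adjusted over the list alone. The median was 1.6 (camera adjusted p = 6.25e-28, adjusted p = 0.0709 with an estimated correlation). The count was 6 without right control 2, 13 without right control 3, 1 without left IFN-alpha-pMC 3 and 761 without the 3 libraries that stood apart.

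The interferon genes themselves were near 0. Among the measured members, Ifna16 had 2 counts in 1 control library, Ifna2, Ifna4, Ifna12 and Ifna13 had 0 in all 18, and Ifnb1 had 17 counts over 12 libraries. The counts of these genes were thus at or near the floor. Pairs that align more than once were not counted, so low counts of the near-identical Ifna genes do not show that their transcripts were absent. The receptor subunit Ifnar2, which stood on the same list, rose on the right from 26.2 ± 1.2 to 38.8 ± 1.83 CPM against control (0.57 ± 0.14, adjusted p = 0.0117, and 0.11 without right control 1), 1 of 2 tested genes over all genes and adjusted over the list alone (median 0.29), and was at 0.07 ± 0.14 on the left.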

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

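The tests of explanations and the counts over other splits of the samples in this part were chosen after the results they address had been seen. The effect of IFN-alpha-pMC relative to pMC differed between right and left tumours, in a test of the difference itself, for 58 genes (edgeR). Killer lymphocyte and T cell genes had the higher effect on the right: Gzma (3.19 ± 0.63, adjusted p = 0.0417), Prf1 (2.79 ± 0.49, adjusted p = 0.0245), Zap70 (2.7 ± 0.47, adjusted p = 0.0241) and Runx3, a transcription factor of CD8 T cells (2.57 ± 0.53, adjusted p = 0.0464). So did Podnl1, a matrix proteoglycan (4.31 ± 0.8, adjusted p = 0.0309), and Nfkbid, a regulator of NF-kappa-B (3.07 ± 0.56, adjusted p = 0.0288), while the effect on Nsdhl was lower on the right (-0.98 ± 0.2, adjusted p = 0.0429). Without left pMC 2 the calls of 6 of these genes ended (adjusted p = 0.134 for Gzma, 0.0965 for Prf1, 0.175 for Runx3, 0.122 for Podnl1, 0.119 for Nfkbid and 0.161 for Nsdhl by edgeR), and that of Zap70 ended without left pMC 3 (adjusted p = 0.089). The count was 0 without right pMC 1 or 2, left pMC 2 or 3, right IFN-alpha-pMC 2 or 3, or left IFN-alpha-pMC 1 or 2, and 36 without left IFN-alpha-pMC 3 (DESeq2 on all libraries called 253). Of 100 splits of the samples 3 gave at least 58 genes, the real one included, with 205 in the highest other, so the share was under 0.05. For the difference relative to control (0 genes by edgeR, 918 at an unadjusted p under 0.05, 86 by DESeq2) the highest other split called 1817. All 100 splits gave as many as the real one, which a real count of 0 fixes, so this says nothing about chance. Splits that call so many more genes than the real one may come from a structure of the samples other than treatment and side. Some splits keep the sides of 1 treatment as they were and so hold part of the real difference, and the cause was not tested.

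Interferon response and lymphocyte genes were higher with IFN-alpha-pMC on both sides by camera with its preset correlation, but with an estimated correlation all of these list results were lost on the left (adjusted p = 0.182 for type I interferon, interferon-gamma and cytotoxic genes and 0.216 for T cell markers, of which 12 of 27 passed by edgeR). A lower share of tumour cells, if nothing else changed, would raise the markers of every other cell type alike. Endothelial markers instead had a median of -0.6 on the right (quartiles -0.86 to -0.24, against 2.72 to 3.1 for T cell markers) and -0.76 on the left (-0.83 to -0.46, against 0.73 to 1.62). That argues against a lower share as the whole cause. A lower share would also lower melanocyte genes. Of 22, 0 were lower at an unadjusted p under 0.05 on the right, and 4 were higher and 3 lower on the left. The fibroblast and muscle lists were higher on both sides by camera with its preset correlation. With the muscle covariate the left fibroblast median was -0.06. The melanocyte genes thus showed no shared fall, but a small lower share could lie within their spread, so it stays open as part of the cause. A trend with transcript length and GC content (fold changes against length over all genes, Spearman rho -0.21 on the right and -0.42 on the left) was examined with the correction. On the right the corrected median over all tested interferon, T cell and cytotoxic genes was 1.74 (116 genes, 1.82 before, median SE 0.3 before and 0.25 after, 101 of 102 calls kept). That argues against the trend as the whole cause on the right. On the left the corrected median was 0.71 for the interferon lists (67 genes, 0.83 before, median SE 0.22 and 0.19, 36 of 43 calls kept) and 1.13 for the T cell and cytotoxic lists (49 genes, 1.42 before, median SE 0.39 and 0.37). Of those left T cell and cytotoxic calls only 15 of 27 stayed and 12 ended, as the median of the called genes fell from 1.77 to 1.55 at a median SE of 0.38 before and 0.36 after, so they are not counted as kept. A first bound on the share of calls kept left both left results undecided, and it was replaced by a bound on the median after those counts were seen. The left medians thus kept most of their size, but no verdict on the trend is drawn for the left. For immune cells carried along with muscle tissue at 1 ratio in all groups, the slope of the T cell score on the muscle score within groups was computed. Over the 6 groups it was -0.08, against 0.86 needed on the right (exact permutation p = 0.000472, one-sided, 46656 orders) and 0.33 on the left (exact permutation p = 0.00538). Over the 3 groups of the side it was -0.16 (exact permutation p = 0.0278) and -0.01 (exact permutation p = 0.0463). These values argue against a straight line with the needed slope between the 2 log2 scores. Carried tissue would add to CPM and not to log2 CPM, and would move the T cell score little where muscle is scarce. The slopes therefore cannot decide on carried tissue itself. In the 3 IFN-alpha-pMC libraries alone the slope was -0.05 on the right and 0.41 on the left, above the 0.33 needed, so muscle richer in immune cells in these mice cannot be told apart from a change in the tumour, because 3 libraries give only 6 orders. A response of the tumours to the cells with the IFN-alpha mark, as more immune cells or as more transcript per cell, and a difference in how the samples were taken may both still account for it, and neither was tested.

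Of the 10 splits of the right control and IFN-alpha-pMC libraries, 2 gave at least the 1601 genes of the real one, and 10 splits are too few for a share under 0.05. The highest other split set right control 3 with IFN-alpha-pMC 1 and 2 against right control 1 and 2 with IFN-alpha-pMC 3. It called 7027 genes (3747 higher and 3280 lower in the first-named set). This is several times the real count, which points to a structure of the samples that is not the treatment. Exchanged labels of right control 3 and IFN-alpha-pMC 3 are argued against by the T cell score of the latter (1.97, with -0.56 in right control 3 and at most -0.14 in right control and pMC libraries). Fold changes of that split fell with transcript length (Spearman rho -0.57, against -0.21 for the real right and -0.42 for the real left comparison with control) and the 177 ribosomal protein genes had a median of 0.96, but 3665 genes still passed with the length and GC correction, which argues against that trend as the whole cause. Another difference in RNA quality or sample handling may remain, and it was not tested.

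Skeletal muscle genes were higher with IFN-alpha-pMC by camera with its preset correlation (medians 2.55 on the right and 2.49 on the left, 7 and 6 of 24 genes past the edgeR threshold), and with an estimated correlation neither list result passed (adjusted p = 0.129 and 0.276). With group means removed, the 24 tested muscle genes, none of which is on another list, moved together across the 18 libraries (median correlation of pairs 0.77, against a 95th percentile of 0.08 in 1000 random sets of genes). Differing amounts of muscle tissue in the dissected samples would give this. Markers picked for 1 tissue can be expected to exceed random sets, and no other list was compared. The correlation shows that muscle transcripts varied together between libraries of a group, but it cannot decide where they came from. Of the abundant muscle genes Ckm was at 188 ± 41.1 against 30.9 ± 36 CPM on the right. A length and GC trend as the whole cause is argued against by medians of 2.58 on the right and 2.61 on the left with the correction. Muscle tissue taken along with the tumours is a candidate explanation, and growth of the tumours into muscle, which was not tested, stays open beside it.

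For the other comparisons of 3 against 3 libraries the 10 splits are likewise too few for a share under 0.05. IFN-alpha-pMC against pMC on the right gave 1497 genes (highest other split 0), and IFN-alpha-pMC against control and against pMC on the left gave 987 and 572 (highest other 0 for both). Right against left gave 375 with IFN-alpha-pMC (highest other 0), 0 in controls (highest other 40) and 0 with pMC (highest other 1) by edgeR, with 116 and 310 genes at an unadjusted p under 0.05 and 0 and 0 by DESeq2. The split calling 40 genes may come from a structure among the control samples, which was not tested. For pMC against control the real split called 0 on each side (highest other 1 on the right and 0 on the left by edgeR, with 359 and 119 genes at an unadjusted p under 0.05 and 2 and 1 by DESeq2).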

How the results depend on the processing

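The removal of 3 libraries that stood apart, the length and GC correction, both together and the muscle covariate were chosen after seeing the data. Of 451 named calls 275 were kept with the muscle covariate. The number was 375 of 449 in a fit of the compared groups alone, 400 with the length and GC correction, 426 without the 3 libraries, 435 with relative log expression scaling and with no filter, 440 of 442 with the stricter filter, 448 of 449 with DESeq2, 449 with upper-quartile scaling and 451 with robust dispersions. No named call reversed in these. For the changes below the cause was not tested.

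The labels do not say whether the sample numbers pair right with left samples, and the data do not settle it: 5 of 9 right libraries correlated best with the left library of their own number. Correlations of same-number right and left libraries were 0.6, 0.12 and -0.02 in controls, 0.1, 0.01 and 0.13 with pMC and 0.3, -0.25 and 0.44 with IFN-alpha-pMC. With the numbers as a block, IFN-alpha-pMC against control gave 0 genes on the right by edgeR (1601 without the block, 2076 with DESeq2) and 1528 on the left (426 higher, 1102 lower), IFN-alpha-pMC against pMC gave 967 and 1835 (722 higher, 1113 lower on the left), pMC against control gave 167 on the left (162 higher), and the difference between sides relative to pMC gave 232. The block kept 291 of 449 named calls.

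Counts of genes moved by more than 1.5 times as follows. DESeq2 called 2 for pMC against control on the right and 1 on the left, 2823 for IFN-alpha-pMC against control and 1984 against pMC on the left, 566 for right against left with IFN-alpha-pMC, and 86 and 253 for the differences between sides relative to control and pMC. A fit of only the compared groups called 582 on the right and 3062 on the left for IFN-alpha-pMC against control, 2538 on the left against pMC, 1 for pMC against control on the left and 190 for right against left with IFN-alpha-pMC. With no filter the difference between sides relative to control gave 7. The length and GC correction gave 2569 for IFN-alpha-pMC against pMC on the right and 14 for the difference between sides relative to control. With the muscle covariate IFN-alpha-pMC gave 970 against control and 754 against pMC on the right, and 147 and 95 on the left.

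Without the 3 libraries the counts were 8175 (IFN-alpha-pMC against control), 5067 (pMC against control) and 4287 (IFN-alpha-pMC against pMC) on the right, 4331 and 4142 (IFN-alpha-pMC against control and pMC) on the left, 1 for right against left in controls, 863 with IFN-alpha-pMC, and 761 for the difference between sides relative to control. With the correction as well they were 6559, 2483 and 4916 on the right and 3077 and 3212 on the left. They were 83 and 25 for the differences between sides relative to control and pMC. The removed libraries also enter the spread that all groups share. For pMC against control on the right, only right control 3 of them was in the compared groups.

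With each library left out in turn, IFN-alpha-pMC against control ranged from 1090 to 3946 on the right (highest without right control 3) and 86 to 494 on the left, and IFN-alpha-pMC against pMC from 1027 to 1893 and 33 to 414. By edgeR pMC against control gave 0 to 1 on the right and 0 on the left. Right against left with IFN-alpha-pMC ranged from 141 to 360, and the differences between sides from 0 to 13 relative to control and 0 to 85 relative to pMC.

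Some lists changed direction by camera, which weighs a list against the other genes, so that its median need not change sign. For pMC against control on the right this was without right control 1, with medians of -0.09 for type I interferon (-0.09 to 0.22 over the libraries left out), -0.11 for T cell (-0.11 to 0.52) and 0.54 for muscle genes (-1.6 to 0.54). On the left it was without left control 1, with -0.06 for type I interferon (-0.06 to 0.11), -0.04 for interferon-gamma (-0.04 to 0.15) and 1.34 for muscle genes (-1.29 to 1.34), and without left pMC 1 with -0.28 for muscle genes. For right against left in controls it was without left control 1 for interferon-gamma (-0.08, range -0.08 to 0.29) and T cell genes (-0.04, range -0.22 to 0.42), without right control 1 for class I (0.21, range -0.16 to 0.21), fibroblast (0.1, range 0.1 to 0.56) and endothelial genes (-0.18, range -0.18 to 0.28), without right control 3 for class II (-0.17, range -0.17 to 0.32) and monocyte genes (-0.16, range -0.16 to 0.5), and without the 3 libraries for monocyte genes (-0.16, and -0.1 with the correction). For right against left with pMC it was without right pMC 1 for T cell genes (0.17, range -0.26 to 0.2). For the difference between sides relative to control it was without the 3 libraries for endothelial (-0.45, and -0.31 with the correction) and erythroid genes (-0.24). With the muscle covariate it was for fibroblast genes on the left (-0.06 for IFN-alpha-pMC against control and -0.02 against pMC).

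Camera with an estimated correlation called 16 of 28 lists higher for IFN-alpha-pMC against control on the right and 17 against pMC. It called 8 for right against left with IFN-alpha-pMC and 0 in the other comparisons, where the preset correlation called 4 to 17 higher. By camera, which weighs a list against the other genes, those list results thus rest on the preset. Fry does not use the preset and does not weigh a list against the other genes. By fry the lists called for IFN-alpha-pMC against control and pMC were 23 and 23 on the right and 19 and 17 on the left. They were 16 for right against left with IFN-alpha-pMC and 4 and 6 for the differences between sides relative to control and pMC. Fry called 0 for pMC against control on both sides and 0 for right against left in control and pMC mice. Depth and the loss of pairs aligned more than once limit the interferon genes, whose mRNAs had too few counts to test (on that list only the receptor genes Ifnar1 and Ifnar2 passed the filter). With 3 libraries per group most changes of 1.5-fold were missed in simulated data.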

Other observations

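In the distant tumours of IFN-alpha-pMC mice further genes changed against left controls (edgeR). Of 22 hypoxia and glycolysis genes 5 rose, 8 adjusted over the list alone (median 0.44, camera adjusted p = 0.00401, adjusted p = 0.296 with an estimated correlation, and camera adjusted p = 0.0691 without left IFN-alpha-pMC 3). Carbonic anhydrase 9, Car9, went from 14.8 ± 2.68 to 40.7 ± 13.6 CPM (1.46 ± 0.33, adjusted p = 0.0228, and 0.0969 without left control 3) and Bnip3 rose by 1.93 ± 0.5 (adjusted p = 0.0384, and 0.142 without left IFN-alpha-pMC 1). Cd274 rose from 64.5 ± 20.2 to 158 ± 25.5 CPM (1.3 ± 0.27, adjusted p = 0.0156, and 0.0923 without left control 1), and 4 of 17 checkpoint genes rose, 8 adjusted over the list alone (median 0.86, camera adjusted p = 8.65e-05, adjusted p = 0.183 with an estimated correlation). Ido1, an enzyme that breaks down tryptophan, had 25 counts against 0 (at least 7.39-fold, adjusted p = 0.0348, and 0.12 without left control 3). Of 11 lymphoid chemokine and structure genes 4 rose, 6 adjusted over the list alone (median 0.95, camera adjusted p = 0.00154, adjusted p = 0.182 with an estimated correlation). Among the falls were the cadherin Celsr2 (23.7 ± 1.99 to 6.57 ± 1.2 CPM, -1.85 ± 0.46, adjusted p = 0.0348, and 0.118 without left control 3) and the transcriptional repressor Tle2 (-3.27 ± 0.65, adjusted p = 0.0123, and 0.07 without left control 3). Against left pMC the clock gene Per1 fell from 154 ± 52.7 to 29.6 ± 6.79 CPM (-2.39 ± 0.42, adjusted p = 0.00989, and 0.0697 without left IFN-alpha-pMC 2).

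Within IFN-alpha-pMC mice the right tumours were also higher in genes of other immune cells (edgeR). Of 14 alternative macrophage activation genes 3 were higher, 10 adjusted over the list alone (median 1.14, camera adjusted p = 1.11e-06, adjusted p = 0.0229 with an estimated correlation), and of 12 plasmacytoid dendritic cell genes 3 were, 5 adjusted over the list alone (median 0.76, camera adjusted p = 3.59e-05, adjusted p = 0.0246 with an estimated correlation). The immunoglobulin heavy chain Ighm was at 29.2 ± 1.01 against 13.6 ± 0.376 CPM (1.11 ± 0.23, adjusted p = 0.0137, and 0.0791 without left IFN-alpha-pMC 1). Lipg, an endothelial lipase, was higher by 3.45 ± 0.55 (adjusted p = 0.00259) and Car4, another carbonic anhydrase, by 4.25 ± 0.62 (adjusted p = 0.00158).

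1 hypothesis was tested after the list results had been seen: that interferon-gamma genes lead in the distant tumour, where the injected cells are not near. The score of the interferon-gamma list minus that of the type I list, less the control mean of the same side, was 0.38 to 0.64 in left and 0.4 to 0.47 in right IFN-alpha-pMC libraries. The left mean was higher by 0.06 (exact permutation p = 0.8, two-sided, smallest possible 0.1), so the test showed no lead, and with 3 libraries per side it could not have passed 0.05.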
